A study of Mus musculus with 15 samples.

How the data were processed

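RNA of mouse embryonic fibroblasts was measured on 15 Agilent whole mouse genome arrays with 2 colours: 4 of wild type, 4 of p27 knock-out, 4 of stathmin knock-out and 3 of double knock-out. Per the labels, the sample was amplified by amino-allyl labelling and carried Cy5 (red), a pool of fibroblast RNA served as the common reference in Cy3 (green), and no dye swap was made. Per the file headers, the deposited scanner files came from Feature Extraction 9.1.3.1 without background subtraction, and their spot signals and local backgrounds are in units of intensity. The deposited ratio of the scanner software is a log10 of dye-normalised red over green. The deposited value table of the authors holds log2 ratios of sample over reference; its normalization is not stated. The log base and direction were read from the values: per array, the table correlated with the scanner ratio at 0.821 to 0.936, with a slope of 0.838 to 0.921 on bright spots once turned to log2.

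Spot intensities were read for 43379 non-control spots per array, which carry 41174 distinct probes. The median sample signal of an array was 251.9 to 452.4 and the median reference signal 339.6 to 400 units; the sample channel was saturated on 0.0945 to 0.265% of spots. In limma 3.58.1 under R 4.3.3, background was corrected by normexp with an offset of 50, ratios were normalised within arrays by loess, and spots marked as outliers by the scanner software (0.0646 to 0.862% per array) were left out. Replicate spots of a probe were averaged. A probe was tested if its sample channel was well above background on at least 3 arrays of at least 1 genotype, which kept 27698 probes and 18708 gene names. Names came from the RefSeq table (GRCm38) through the accession for 18204 probes, the current symbol for 4017 and an older symbol for 1906; 3571 kept the name in the file. The brightest tested probe stood for each gene.

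All 15 arrays were fitted together in limma with a mean per genotype (11 residual degrees of freedom). The 6 comparisons were p27, stathmin and double knock-out against wild type, double knock-out against each single knock-out, and the interaction. All tests were two-sided unless stated otherwise; p-values were moderated by limma, corrected by the Benjamini-Hochberg method over genes, and called at an adjusted p under 0.05. Intervals are at 95%. The labels call the arrays of a genotype biological replicates, and every p-value treats them as such. The labels' replicate numbers were not used to pair the samples in the main fit. Pairs of arrays with the same number had residual correlations from -0.259 to 0.415, with 12 of 21 over 0.1. Of 15 arrays, 5 were closest to an array of their own number. Whether the numbers pair the samples was not tested, and replicate number was a block in an alternative fit. The slide of each array, of which there were 4, was used as a block in an alternative fit.

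Named genes were chosen by a rule: Cdkn1b and Stmn1 in every comparison, genes past the threshold with a symbol, and, where fewer than 5 passed, the 10 symbols with the smallest p. Members of lists given as examples are among those with the smallest p in their list or passed when adjusted over the list alone, and were chosen after their values were seen. Genes were also tested in 37 lists on the cell cycle, cytoskeleton, matrix, signalling, stress, metabolism, patterning and markers of other cell types. Lists were tested by camera with an inter-gene correlation estimated from the data, corrected over the 37 lists. A gene said to pass when adjusted over the list alone is not corrected over the 37 lists or the 6 comparisons. Such passes came in 2, 2, 1, 3, 4 and 5 of the 37 lists in the 6 comparisons in turn. Where no gene changes, about 1 in 20 lists may still give one. Camera with a preset correlation of 0.01 compares a list with other genes under a fixed value; fry tests whether the genes of a list move on balance one way and does not compare them with other genes. Genes, lists, comparisons and the tests named so far were fixed before the data were examined.

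The fit and the list test were tested on simulated data of the same size, with genes drawn independently of each other. In each comparison 100 genes changed 2-fold and 100 genes changed 4-fold were simulated together. Limma recovered 43 to 58.2% of those changed 2-fold in the comparisons of 2 genotypes. Camera with an estimated correlation called the 1 list that was moved in each of the 6 comparisons. Genes without correlation cannot show how often camera would find a change in a list of correlated genes. Alternatives covered background correction, normalization, the filter on dim probes, the probe that stands for a gene, replicate and slide blocks, array weights, the variance model, the arrays in the fit and leaving out each array in turn. Terms for the sex-linked pattern, only arrays with low Xist, wild type 3 and 4 averaged, and the sample channel alone were added after seeing the data. For the sample channel alone, log2 signals after normexp were given equal quantiles across arrays, and the reference channel was treated in the same way. Each count was compared with other splits of the same arrays, 35 per comparison and 100 drawn for the interaction. Grouping of arrays was tested by 100000 permutations of the labels. Figures were drawn with matplotlib. Genes tested only on probes near background were left out.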

Results

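Gene expression was measured in mouse embryonic fibroblasts of 4 genotypes: wild type (4 arrays), p27 knock-out (4 arrays), stathmin knock-out (4 arrays) and double knock-out lacking both genes (3 arrays). p27, made from Cdkn1b, is an inhibitor of cyclin-dependent kinases, and stathmin, made from Stmn1, is a protein that destabilises microtubules. The cells came from embryos at 13.5 days, were at passage 3 and high confluence, and were kept for 24 h without serum. The labels call the arrays of a genotype biological replicates. Each array compared a sample in the red dye with a pooled fibroblast reference in the green dye, so every value is a log2 ratio of sample to reference. The sample channel was well above background on 59.3 to 78.9% of the spots of an array, with a median of 66.5%. Between 18679 and 18708 genes could be tested per comparison, and the number of arrays limits the precision: the median 95% interval of a log2 difference reached 0.48 to 0.70 to either side.

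The arrays did not group by genotype. The mean correlation across genes was 0.159 between arrays of 1 genotype and 0.16 between arrays of different genotypes (permutation test, one-sided, p = 0.478; adjusted p = 0.478 over 3 groupings). Arrays of 1 slide had a mean correlation of 0.204 against 0.149 for other pairs (permutation p = 0.139; adjusted p = 0.208). Genes of the Y chromosome were low and Xist was high on 4 arrays, namely double knock-out 1, p27 knock-out 2, and stathmin knock-out 1 and 2. Wild type 1 carried both signals, and the other 10 arrays had low Xist. Arrays alike in this pattern had a mean correlation of 0.227 against 0.097 for other pairs (permutation p = 0.0318, adjusted p = 0.0953). The pattern was read from genes of these same arrays that also entered the correlations, so part of this difference may be built in. The pairs alike in it include wild type 3 and 4, at 0.815. Correlations across genes describe the arrays only, since genes are not independent replicates. Each slide held 1 array per genotype, except for 1 slide without a double knock-out, and a genotype always had the same position on the slide, so position and genotype cannot be told apart.

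The second Stmn1 probe gave a low signal on all 7 arrays that lack the gene. Its mean log2 ratio was 0.76 ± 0.10 (SD, n = 4) in wild type, 0.94 ± 0.48 (n = 4) in p27 knock-out, -2.78 ± 0.15 (n = 4) in stathmin knock-out and -2.77 ± 0.08 (n = 3) in double knock-out. It fell by 3.53 on the log2 scale in stathmin knock-out against wild type (SE 0.193, adjusted p = 1.75e-06, lower on 4 of 4 arrays) and fell by 3.52 in double knock-out against wild type (SE 0.208, adjusted p = 5e-06, lower on 3 of 3 arrays). Against p27 knock-out, the double knock-out fell by 3.71 (SE 0.208, adjusted p = 2.56e-06, lower on 3 of 3 arrays). The brighter Stmn1 probe, which stood for the gene in the gene-level counts, read -0.10 ± 0.34 in wild type (n = 4) and -0.51 ± 0.36 in stathmin knock-out (n = 4), a difference of -0.41 that did not pass (SE 0.291, adjusted p = 0.911, below all wild type arrays on 2 of 4). Cdkn1b, on chromosome 6, was read by 1 tested probe: 0.22 ± 0.50 in wild type (n = 4), -0.34 ± 0.52 in p27 knock-out (n = 4), -0.08 ± 0.40 in stathmin knock-out (n = 4) and -0.75 ± 0.83 in double knock-out (n = 3). The difference of -0.56 between p27 knock-out and wild type did not pass (SE 0.364, adjusted p = 0.798), and neither did that of -0.97 between double knock-out and wild type (SE 0.393, adjusted p = 1). The dimmest Cdkn1b probe, too near background to be tested, read between 0.22 and 0.36 on the wild type arrays and between -0.20 and -0.10 on the p27 knock-out arrays. On that probe the stathmin knock-out arrays read between -0.13 and 0.53, and the double knock-out arrays between -0.18 and -0.08. Another Cdkn1b probe near background read between -0.13 and -0.01 in wild type and between -0.33 and 0.36 in p27 knock-out. Where the knock-out alleles alter the genes relative to these probes is not given in the labels.

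**Figure D1:**
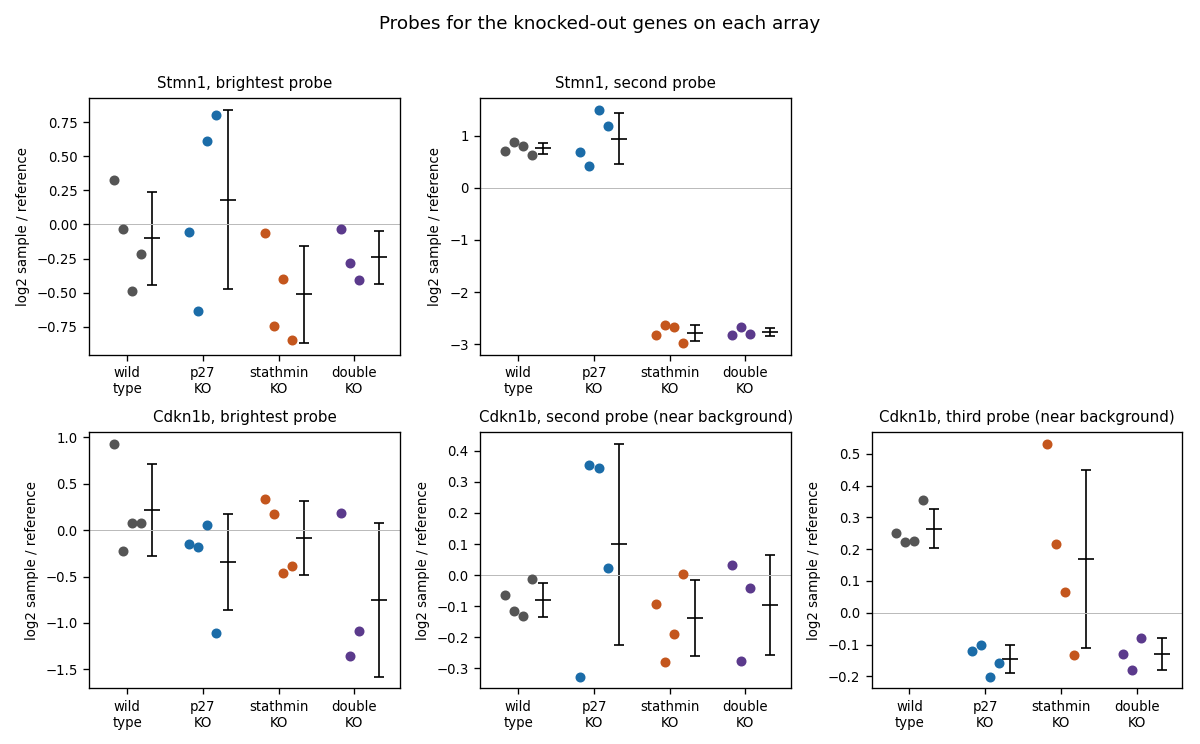
Log2 ratio of sample to reference for each tested Stmn1 probe and for the 3 Cdkn1b probes, with 1 point per array and the mean ± SD beside the points of each genotype. On the second Stmn1 probe the 7 arrays without stathmin lie between -2.98 and -2.64, while wild type arrays lie between 0.64 and 0.87.

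The first comparison asked what loss of p27 alone changes in serum-starved fibroblasts. Of the named genes, 0 passed over all genes. Lce1i and Lce1h, which encode proteins of the cornified envelope, differed by -2.30 (SE 0.418) and -2.23 (SE 0.415) on the log2 scale, each below every wild type array on 4 of 4 p27 knock-out arrays (adjusted p = 0.636 for each). The simple-epithelium keratin Krt7 differed by -1.61 (SE 0.306, adjusted p = 0.636, 4 of 4 arrays), and it passed when adjusted over the list alone. Krt7 had 2 tested probes, and only the brighter one is given here and in the other comparisons. The largest difference among the named genes was that of Pbp2, a phosphatidylethanolamine-binding protein gene on the chromosome of Cdkn1b, at -3.82 (SE 0.67, adjusted p = 0.636, 4 of 4 arrays). Ddb2, a DNA damage recognition gene and p53 target, differed by 0.88 (SE 0.202, adjusted p = 0.798, higher on 4 of 4 arrays) and passed when adjusted over the list alone.

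Limma called 0 of 18679 genes changed between p27 knock-out and wild type, while 1074 genes had an unadjusted p under 0.05, 482 higher and 592 lower. The slide block, a limma fit with slide as a term, also called 0, with 1494 genes at an unadjusted p under 0.05. The other named genes differed with the same direction on all 4 slides: Gabra4, a GABA receptor subunit (-1.15), Lce1e (-0.97), Bmp8b, a bone morphogenetic protein (-0.87), Pde6h, a photoreceptor phosphodiesterase subunit (-1.19), and Apobec1, an RNA-editing deaminase (1.16). Their adjusted p was 0.798, and Bmp8b was well above background on only 1 of 4 p27 knock-out arrays. In simulated data of this design, limma recovered 47% of genes changed 2-fold and 91.9% of those changed 4-fold. With 100 genes of each kind changed at once, the adjusted threshold is easier to reach than with few changed genes. These shares therefore do not hold where few genes change.

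Of the 37 lists fixed beforehand, 0 were called with an estimated correlation. All 39 measured members of the interferon response had a log2 difference above 0 in p27 knock-out, with a median of 1.71, and 0 of the 39 were called. Psmb9, an immunoproteasome subunit, differed by 1.81 (SE 0.577), Tap1, the peptide transporter of antigen presentation, by 1.34 (SE 0.468), and the tethering factor Bst2 by 1.78 (SE 0.661). The list mean was -1.62 ± 0.12 (SD, n = 4) in wild type and 0.08 ± 1.58 (n = 4) in p27 knock-out, whose 4 arrays read 1.64, 1.19, -0.90 and -1.61, the last within the wild type range of -1.74 to -1.46. Camera with a preset correlation called the list (adjusted p = 1.52e-18), and the call was lost at adjusted p = 0.592 with an estimated correlation. Macrophage and blood markers had 25 of 25 members above 0, with a median of 0.92 (adjusted p = 0.852 with an estimated correlation). Their mean was 1.83 on p27 knock-out 2 but -2.74 on p27 knock-out 3, the array with the highest interferon mean. Epithelial markers had 11 of 13 members below 0, with a median of -0.46, 0 of 13 called over all genes, and adjusted p = 0.385 with an estimated correlation, the smallest of the 37 lists. Within slides the epithelial difference ran from -1.20 to 0.15. Camera called 0 of 37 lists with an estimated correlation and 14 with a preset one, 3 lists had an unadjusted p under 0.05, and fry called 0 (smallest adjusted p = 0.254).

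**Figure D2:**
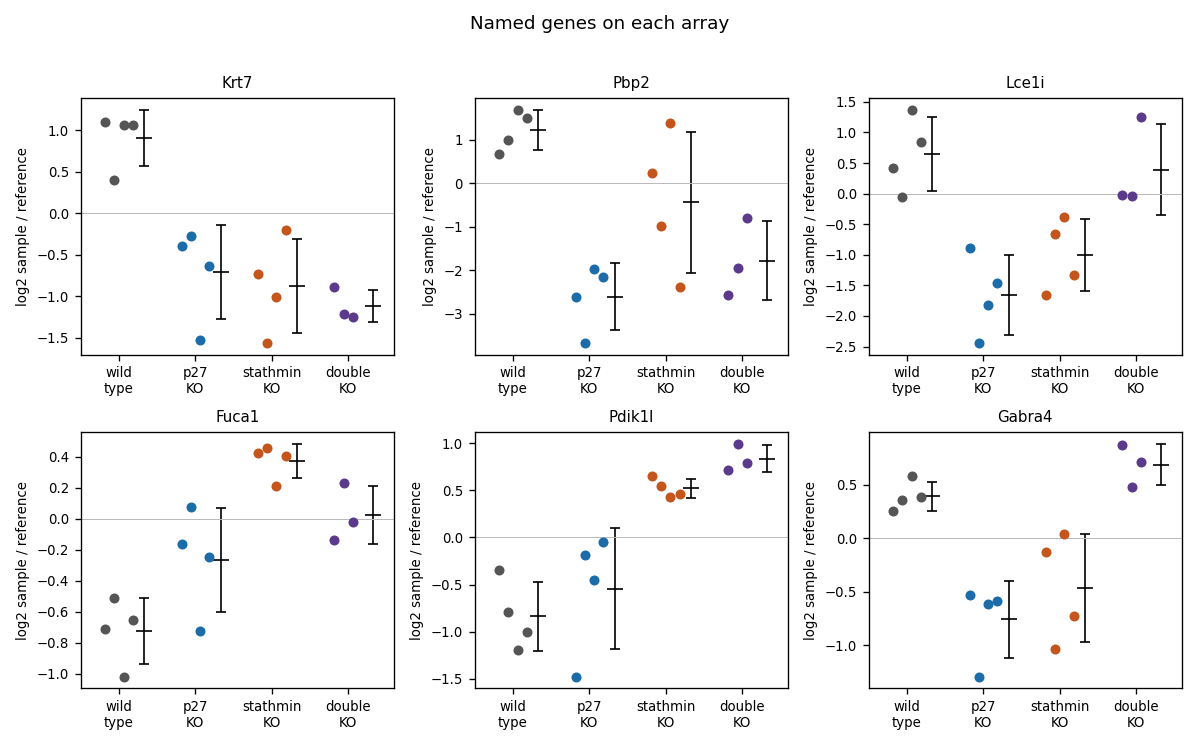
Log2 ratio of sample to reference of 6 named genes, with 1 point per array and the mean ± SD beside the points of each genotype. Krt7 lay at or below -0.20 on every array without p27 or stathmin and at or above 0.40 on the wild type arrays; of the genes drawn, 0 passed over all genes.

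The comparison of stathmin knock-out with wild type asked what loss of stathmin alone changes. The ribosomal protein gene Rpl11 had a lower ratio on all 4 stathmin knock-out arrays: -0.13 ± 0.35 (SD, n = 4) against 1.55 ± 0.29 (n = 4), a log2 difference of -1.68 (SE 0.196, 95% interval -2.10 to -1.26, adjusted p = 0.0146, 4 of 4 arrays). Rpl11 lies on chromosome 4 at 136049354 (GRCm38), on the chromosome of Stmn1, which starts at 134468320. Among the next named genes, Fuca1, a lysosomal fucosidase, differed by 1.10 (SE 0.169, adjusted p = 0.153), and the kinase gene Pdik1l by 1.36 (SE 0.266, adjusted p = 0.419), each above all wild type arrays on 4 of 4. The other Pdik1l probe differed by -0.56 (SE 0.222), opposite in sign, and the other Fuca1 probe by 0.45 (SE 0.192), with the same sign. Asap3, which encodes an Arf GTPase-activating protein, differed by 1.96 (SE 0.357, adjusted p = 0.289, 4 of 4 arrays). Fuca1, Pdik1l and Asap3 lie on chromosome 4 as well.

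Limma called 1 of 18686 genes, Rpl11, and 889 had an unadjusted p under 0.05, 367 higher and 522 lower. Within slides the Rpl11 difference ran from -1.89 to -1.41, and with the slide block its adjusted p was 0.00079; that fit called 2 genes. Most of the Rpl11 ratio difference lay in the reference channel, which per the labels carried RNA from pooled fibroblasts. The raw Rpl11 reference signal was 61500 to 123000 in wild type and 156000 to 225000 in stathmin knock-out, while the sample signal was 450000 to 591000 and 353000 to 473000. Tested alone, the Rpl11 sample channel differed by -0.47 (SE 0.139, adjusted p = 0.98) and the reference channel by 1.21 (SE 0.154, adjusted p = 0.0385). The Rpl11 call was also lost with only the genotypes compared in the fit (adjusted p = 0.368), and without wild type 1, 2 or 3 or stathmin knock-out 2 or 3 in turn (adjusted p = 0.0663 to 0.107). Over all alternatives its adjusted p ran from 0.00079 to 0.98, and over those that kept the ratio its difference stayed between -1.89 and -1.56. The second, dimmer Rpl11 probe differed by 0.51 (SE 0.471), opposite in sign.

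**Figure D3:**
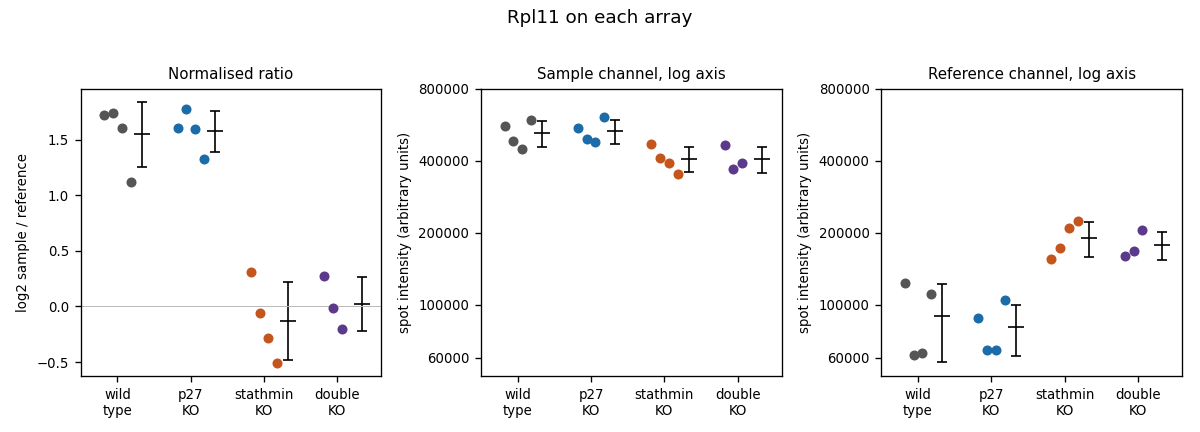
Rpl11 on each array: normalised log2 ratio, and raw intensity of the sample and reference channels on log axes in arbitrary units, with the mean ± SD beside the points of each genotype. The reference channel reached at most 123000 on arrays with stathmin and at least 156000 on arrays without it.

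Other named genes in stathmin knock-out were the zinc finger gene Tshz1 at -0.70 (SE 0.113, adjusted p = 0.157), the keratins Krt7 at -1.78 (SE 0.306, adjusted p = 0.245) and Krt80 at -1.19 (SE 0.24, adjusted p = 0.473), and Lce1e at -0.86. Catsper2, a sperm cation channel subunit, differed by 0.60 and Rapgef3, an exchange factor activated by cyclic AMP, by 0.68. Each of these lay beyond all wild type arrays on 4 of 4 stathmin knock-out arrays. Of 55 mitosis genes 54 were below 0, with a median of -0.68 and 0 called; Cenpa, the centromeric histone, differed by -1.42 (SE 0.46) and Birc5, a survivin gene of the chromosomal passenger complex, by -1.03 (SE 0.389). Of 39 DNA replication genes 38 were below 0, with a median of -0.41 and 0 called, among them Pola1, a DNA polymerase subunit, at -0.79 (SE 0.308). Within slides the DNA replication difference ran from -1.11 to 0.09, and the lowest array mean, -1.02, was that of stathmin knock-out 2. All 25 cholesterol synthesis genes were below 0, with a median of -0.47 and 0 called; Nsdhl, a sterol dehydrogenase, differed by -0.75 (SE 0.256), and within slides the list ran from -1.07 to 0.20. Each of these 3 lists was called with a preset correlation and had adjusted p = 0.478 with an estimated correlation. The mitosis mean was 0.17 ± 0.29 (SD, n = 4) in wild type and -0.50 ± 0.64 (n = 4) in stathmin knock-out, where arrays 1 to 4 read -0.04, -1.39, -0.01 and -0.55, and within slides its difference ran from -1.54 to 0.03. The E2F transcription factor gene E2f2 (-0.86), which promotes S-phase entry, and the keratins Krt19 (-0.99) and Krt7 passed when adjusted over the list alone. E2f2, like Rpl11, lies within 50 tested genes of Stmn1, so its difference may belong to the neighbourhood of the knocked-out gene. The interferon list had 38 of 39 members above 0, with a median of 1.25 and 0 called (adjusted p = 0.478 with an estimated correlation), and its stathmin knock-out arrays read from -1.45 to 1.34. Neuronal and glial markers had 17 of 21 members below 0, with a median of -0.47 and the smallest adjusted p of the lists, 0.236. Camera called 0 of 37 lists with an estimated correlation and 13 with a preset one, 3 had an unadjusted p under 0.05, and fry called 0 (smallest adjusted p = 0.24).

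The comparison of double knock-out with wild type asked what loss of both genes changes. Krt7 was lower on 3 of 3 double knock-out arrays, at -1.12 ± 0.20 (SD, n = 3) against 0.91 ± 0.34 (n = 4), a difference of -2.02 (SE 0.331, adjusted p = 0.294), and it passed when adjusted over the list alone. Rpl11 differed by -1.53 (SE 0.211, adjusted p = 0.103, below all wild type arrays on 3 of 3); its reference channel alone differed by 1.02 and its sample channel by -0.48. The dimmer Rpl11 probe differed by 0.08 (SE 0.509). Pdik1l differed by 1.67 (SE 0.287, adjusted p = 0.322), Asap3 by 1.59 (SE 0.386, adjusted p = 1) and Fuca1 by 0.75 (SE 0.182, adjusted p = 1), each above all wild type arrays on 3 of 3. The other Pdik1l probe differed by -0.38 (SE 0.24), opposite in sign, and the other Fuca1 probe by only 0.04 (SE 0.208). Pbp2 differed by -2.99 (SE 0.724, adjusted p = 1) and Irx3, a homeobox transcription factor gene, by -1.13 (SE 0.257, adjusted p = 1), each below all wild type arrays on 3 of 3.

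Limma called 0 of 18686 genes changed between double knock-out and wild type, with 435 at an unadjusted p under 0.05; the slide block called 1, Rpl11 (adjusted p = 0.00748), with 580 at an unadjusted p under 0.05. Within slides Rpl11 differed by -1.62 to -1.32. The remaining named genes were Clmn (-0.83), Efcab7 (1.42) and H2-T10, a class Ib histocompatibility gene with a value on only 1 double knock-out array. Epithelial markers had 11 of 13 members below 0, with a median of -0.35 and 0 called over all genes: besides Krt7, the desmosomal genes Dsp and Perp differed by -1.40 (SE 0.455) and -1.56 (SE 0.642). This list was called with a preset correlation and had adjusted p = 0.25 with an estimated correlation, and within slides its difference ran from -0.79 to -0.32. Collagen genes had 26 of 29 members below 0, with a median of -0.30 and 0 called (adjusted p = 0.469 with an estimated correlation); Col6a3 differed by -0.79 (SE 0.235), and within slides the list ran from -0.39 to 0.01. The interferon list had 39 of 39 members above 0, with a median of 0.85 and 0 called (adjusted p = 0.889 with an estimated correlation). Its double knock-out arrays read 0.43, -1.09 and -1.65, the last within the wild type range, so the difference rested mostly on double knock-out 1. Macrophage and blood markers had 25 of 25 members above 0, with a median of 0.73 (adjusted p = 0.889 with an estimated correlation), but their mean ran from -2.32 to 1.43 on the double knock-out arrays, and within slides the sign differed, from -0.50 to 2.35. Mitosis genes split into 24 above and 31 below 0, with a median of -0.04. The homeobox and the neuronal lists had a median above 0 while the test pointed down. Camera called 0 of 37 lists with an estimated correlation and 9 with a preset one, 3 had an unadjusted p under 0.05, and fry called 0 (smallest adjusted p = 0.332).

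**Figure D4:**
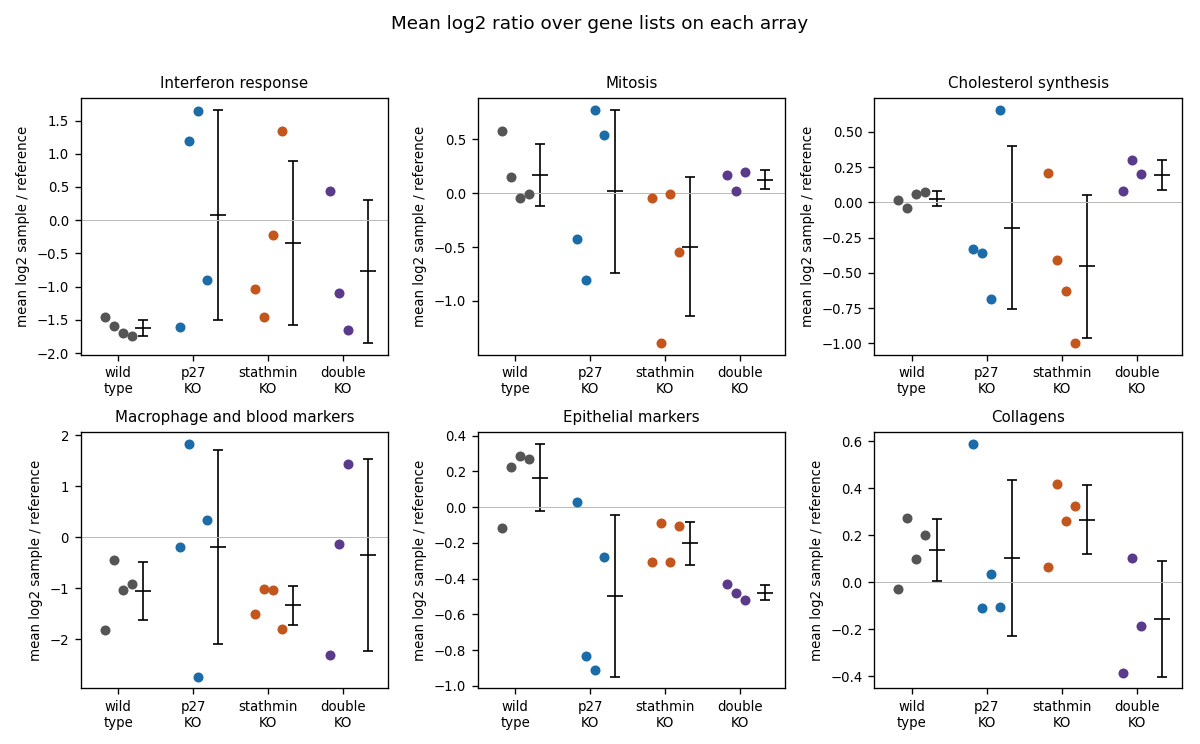
Mean log2 ratio of sample to reference over the genes of 6 lists, with 1 point per array and the mean ± SD beside the points of each genotype. The interferon mean lay between -1.74 and -1.46 on the wild type arrays and between -1.65 and 1.64 on the others.

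The comparison of double knock-out with p27 knock-out asked what losing stathmin changes where p27 is already absent. Gabra4 was higher on 3 of 3 double knock-out arrays, at 0.69 ± 0.20 (SD, n = 3) against -0.76 ± 0.36 (n = 4), a difference of 1.45 (SE 0.252, adjusted p = 0.562). The cornified envelope genes Lce1i and Lce1h differed by 2.04 (SE 0.451) and 1.90 (SE 0.448), and Pdik1l by 1.38 (SE 0.287), each above all p27 knock-out arrays on 3 of 3 (adjusted p = 1). The other Pdik1l probe differed by -0.30 (SE 0.24), opposite in sign. Col6a3, a collagen chain, differed by -1.03 (SE 0.235, adjusted p = 1, below on 3 of 3). Its sample channel alone differed by -0.52 (SE 0.142) and its reference channel by 0.45 (SE 0.167). Much of the Col6a3 difference thus lay in the reference, and its channels in the other comparisons are not given here. Among relatives of stathmin, Stmn2 differed by -1.85 and Stmn4 by 1.71, and both passed when adjusted over the list alone, as did Col6a3 and the plasminogen activator gene Plat (0.92). Rpl11 differed by -1.55 (SE 0.211, adjusted p = 0.0844, below on 3 of 3), with its reference channel at 1.08 and its sample channel at -0.41. The sample signal of that spot was saturated on 1 of 4 p27 knock-out arrays, so these values are uncertain. The dimmer Rpl11 probe differed by 0.21 (SE 0.509).

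Limma called 0 of 18701 genes changed between double knock-out and p27 knock-out, with 555 at an unadjusted p under 0.05; the slide block called 1, Rpl11 (adjusted p = 0.00626), with 469 at an unadjusted p under 0.05. Within slides Rpl11 differed by -1.61 to -1.33. Lingo2 (2.75), Clmn (-0.97), Abca2, a lipid transporter (-0.69), and Clec12b were the remaining named genes, at adjusted p = 1. Clec12b was well above background on 0 of 4 p27 knock-out arrays, so the size of its difference is uncertain. It differed by 1.17 on the log2 scale (SE 0.28), and within slides by 0.48 to 2.17. Of 23 genes of the actin and serum response factor list 20 were above 0, with a median of 0.51 and 0 called; Tagln, a smooth-muscle actin-binding protein, differed by 1.67 (SE 0.776). The list had adjusted p = 0.614 with an estimated correlation, and within slides it ran from -0.90 to 1.24. Cholesterol synthesis genes had 23 of 25 members above 0, with a median of 0.37 and 0 called, among them Hmgcs1, hydroxymethylglutaryl-CoA synthase, at 1.03 (SE 0.385), and adjusted p = 0.614 with an estimated correlation. Within slides the cholesterol difference ran from -0.46 to 0.98, since p27 knock-out 4 had the highest mean of these arrays. The interferon list had 38 of 39 members below 0, with a median of -0.80 (adjusted p = 0.818 with an estimated correlation; -2.73 to 2.04 within slides), and the epithelial list had a median below 0 while the test pointed up. Camera called 0 of 37 lists with an estimated correlation and 14 with a preset one, 1 had an unadjusted p under 0.05, and fry called 0 (smallest adjusted p = 0.751).

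The comparison of double knock-out with stathmin knock-out asked what losing p27 changes where stathmin is already absent. All 25 cholesterol synthesis genes were above 0, with a median of 0.61 and 0 called; Hmgcs1 differed by 1.19 (SE 0.287) and Lss, lanosterol synthase, by 1.08 (SE 0.359). Of 55 mitosis genes 54 were above 0, with a median of 0.68, and of 39 DNA replication genes 38, with a median of 0.53, with 0 called in each. Collagens had 26 of 29 members below 0, with a median of -0.32. The list means were 0.19 ± 0.11 (SD, n = 3) against -0.46 ± 0.51 (n = 4) for cholesterol synthesis and 0.13 ± 0.09 (n = 3) against -0.50 ± 0.64 (n = 4) for mitosis.

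Each of these 4 lists was called with a preset correlation. With an estimated correlation the calls were lost: adjusted p = 0.356 for cholesterol synthesis, 0.428 for mitosis and for DNA replication, and 0.235 for collagens. Within slides the cholesterol difference ran from -0.13 to 1.19, that of mitosis from 0.03 to 0.74, that of DNA replication from -0.10 to 0.76 and that of collagens from -0.51 to -0.16. The slide without a double knock-out held stathmin knock-out 2, which had the lowest mitosis mean, -1.39. The collagen genes Col6a3 (-0.93), Col6a1 (-0.88), Col6a2 (-0.68), Col5a3 (-1.28) and Col18a1 (-1.20) passed when adjusted over the list alone, and so did the limb patterning genes Hoxd13 (-1.95), Hoxd10 (-1.15) and Hoxd11 (-1.06), although 25 of 36 Hox genes were above 0. The transcription factor gene Tcf7 (-1.24) and the death receptor gene Tnfrsf10b (-0.59) passed likewise. Neuronal and glial markers had 16 of 21 members above 0, with a median of 0.59 (adjusted p = 0.235 with an estimated correlation), among them Fabp7, a fatty acid-binding protein of glia, at 1.73 (SE 0.533). Macrophage and blood markers had 25 of 25 members above 0, with a median of 1.02 (adjusted p = 0.583 with an estimated correlation); their mean ran from -2.32 to 1.43 on the double knock-out arrays and from -1.80 to -1.01 on the stathmin knock-out arrays. Limma called 0 of 18708 genes, with 728 at an unadjusted p under 0.05, and the slide block also called 0, with 590. The named genes with the smallest p were the kinase gene Pak7 at 1.00 (SE 0.196), Tcf7, Clmn at -0.93, Tmem171 at 1.38, the guidance receptor gene Robo1 at -1.38, Gabra4 at 1.15, Tshz1 at 0.54, Dzip1 at -1.02 and Clec12b, each beyond all stathmin knock-out arrays on 3 of 3 (adjusted p = 1). Clec12b was well above background on 0 of 4 stathmin knock-out arrays and Pak7 on 1 of 4, so the sizes of their differences are uncertain. Clec12b differed by 1.225 (SE 0.28), and within slides by 0.56 to 2.15. H2-T10 had a value on only 1 double knock-out array. Camera called 0 of 37 lists with an estimated correlation and 17 with a preset one, 4 had an unadjusted p under 0.05, and fry called 0 (smallest adjusted p = 0.311).

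The interaction asked whether losing both genes differs from the sum of the single losses. Gabra4 had the smallest p: it read -0.76 ± 0.36 (SD, n = 4) in p27 knock-out and -0.47 ± 0.50 (n = 4) in stathmin knock-out, but 0.69 ± 0.20 (n = 3) in double knock-out and 0.39 ± 0.14 (n = 4) in wild type. Its interaction was 2.31 (SE 0.344, adjusted p = 0.227, same sign on 3 of 3 slides), and it was well above background on 3 of 4 arrays of each single knock-out. Lce1i (3.70, SE 0.615, adjusted p = 0.325) and Lce1h (3.55, SE 0.611, adjusted p = 0.325) also had lower means in each single knock-out than in wild type and double knock-out; double knock-out lay above wild type for Gabra4 and below it for these 2. Tshz1 had an interaction of 0.92 (SE 0.166, adjusted p = 0.378) and Lce1e one of 1.62 (SE 0.301, adjusted p = 0.425).

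Limma called 0 of 18679 genes for the interaction, with 1372 at an unadjusted p under 0.05, and the slide block called 0 with 1334. Limma recovered 21% of interactions simulated at 2-fold and 69.7% of those at 4-fold, again with 100 genes of each kind changed at once. The proto-oncogene Mycn (4.02), Lingo2 (3.59), the complement receptor gene Cr2 (1.46), Dzip1 (-1.48) and Lhpp (-0.99) had adjusted p = 0.647. Cr2 was well above background on 2 of 4 wild type, 1 of 4 p27 knock-out and 1 of 4 stathmin knock-out arrays, so its value is uncertain. Cholesterol synthesis genes had 25 of 25 members above 0, with a median of 0.92, DNA replication 39 of 39, with a median of 0.60, and mitosis 54 of 55, with a median of 0.80, with 0 called in each. Their adjusted p with an estimated correlation was 0.445, 0.445 and 0.522. Within slides they ran from 0.22 to 1.67, from -0.15 to 0.56 and from -0.78 to 1.22. These ranges leave out the slide without a double knock-out, whose arrays do enter the medians and the counts of members. Stathmin knock-out 2 of that slide had the lowest mean of its genotype for DNA replication, -1.02, and for mitosis, -1.39. The interferon list had 39 of 39 members below 0, with a median of -2.17 (adjusted p = 0.445 with an estimated correlation), and within slides it ran from -4.21 to 1.61. Neuronal and glial markers had 17 of 21 members above 0, with a median of 0.69 and the smallest adjusted p of the lists, 0.193 with an estimated correlation. Stmn4 (2.22), the small GTPase gene Rhoq (-0.71), Ddb2 (-1.21), Krt19 (1.45), Krt18 (3.27), Krt7 (1.37) and the neuronal RNA-binding protein gene Elavl4 (2.11) passed when adjusted over the list alone. Camera called 0 of 37 lists with an estimated correlation and 16 with a preset one, 3 had an unadjusted p under 0.05, and fry called 0 (smallest adjusted p = 0.0948). The median and the mean log2 difference of a list differed in sign for 6, 5, 2, 5, 1 and 8 lists in the 6 comparisons in the order given here.

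The changes of the knock-outs against wild type were correlated across genes, and all 3 use the same wild type arrays. The correlation was 0.733 between p27 and stathmin knock-out, 0.555 between p27 and double knock-out and 0.393 between stathmin and double knock-out. Independent groups that share a wild type group gave 0.501, 0.465 and 0.463 in simulation. In simulated arrays 95% of the correlations lay between 0.00633 and 0.814, -0.0855 and 0.828, and -0.288 and 0.822, so each observed value is inside the range that independent groups gave. With each knock-out set against a different pair of wild type arrays, the means were 0.458, 0.285 and 0.124. Wild type 3 and 4, the closest pair of arrays (correlation 0.815), fell on different sides in most of these splits. Both knock-outs may thus still share much of their control, and no range from independent groups was simulated for these means.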

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

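The rule for single arrays was fixed before the data were examined; no test of an explanation was made for these values. An array is listed where its gap to the nearest of the other 3 arrays of its genotype, divided by the range, was above Dixon's critical value at 95%. Of 222 groups of 4 values, 16 were above it (7.21%), 8 for genes and 8 for lists, where chance gives about 1 in 20. The double knock-out has 3 arrays and was not tested.

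Krt7 read 0.40 on wild type 2, with the other wild type arrays from 1.06 to 1.10. Gabra4 read -1.30 on p27 knock-out 2, against -0.62 to -0.53 on the others. Apobec1 read -0.17 on p27 knock-out 1 (others 0.73 to 0.85), Tshz1 0.23 (others -0.06 to -0.03) and Robo1 -0.46 (others 0.37 to 0.50) on that array. Lingo2 read -3.77 (others -1.48 to -1.08) and Dzip1 0.95 (others 0.17 to 0.30) on p27 knock-out 2. Catsper2 read -0.44 on wild type 3 (others -0.14 to -0.10).

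Among lists, the mean of the inhibitors of cyclin-dependent kinases was 0.32 on stathmin knock-out 1 (others -0.34 to -0.27), and that of inflammatory and secretory genes was -2.11 on the same array (others 0.10 to 0.52). Genes of the Wnt pathway read 0.35 on stathmin knock-out 2 (others -0.36 to -0.34). Hypoxia and glycolysis genes read -0.16 on wild type 2 (others -0.43 to -0.40), and oxidative stress genes -0.46 on wild type 1 (others -0.19 to -0.14). Adipocyte markers read -0.25 on wild type 2 (others -0.58 to -0.55) and 0.93 on p27 knock-out 2 (others -0.33 to -0.14). Epithelial markers read -0.12 on wild type 1 (others 0.22 to 0.28).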

How the results depend on the processing

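The alternatives with terms for the sex-linked pattern, only arrays with low Xist, wild type 3 and 4 averaged, and the sample channel alone were chosen after seeing the data. Values are counts of genes changed, against 0, 1, 0, 0, 0 and 0 in the 6 comparisons in the order of the text. In double knock-out against wild type and against p27 knock-out, the scanner software ratio, the series matrix values, the replicate block, the slide block and slide as a random block each gave 1 and 1 (Rpl11), and all probes gave 1 and 1 (Stmn1). In stathmin knock-out against wild type, all probes gave 2, the slide block 2, the replicate block 3 (Rpl11, Fuca1 and an unnamed transcript), only arrays with low Xist 6, and only the genotypes compared 0, as did the sample channel alone, with Rpl11 at -0.47. Array weights gave 11 in stathmin knock-out and 11 in double knock-out against wild type, 1 in double against p27 knock-out (Rpl11) and 1 in the interaction (Gabra4). Terms for the sex-linked pattern gave 1 in double against p27 knock-out (Rpl11) and put the brighter Stmn1 probe at 0.058 in double knock-out against wild type, where it was -0.14; without single arrays it ran from -0.27 to 0.0043. Without single arrays the counts ran from 0 to 2 in stathmin knock-out against wild type and from 0 to 1 in the 4 later comparisons. The counts of 2 came without p27 knock-out 1 (Pdik1l added), p27 knock-out 3 (Fuca1) or stathmin knock-out 4 (Fn3krp); counts of 0 came without wild type 1, 2 or 3 or stathmin knock-out 2 or 3. In double knock-out against wild type 1 gene came without p27 knock-out 1 (Pdik1l), stathmin knock-out 1 or wild type 4 (Rpl11), and in double against p27 knock-out without stathmin knock-out 1 or wild type 4 (Rpl11). Fn3krp was called without stathmin knock-out 4 in double against stathmin knock-out and in the interaction, and Hoxa5 without p27 knock-out 1 in the interaction. Lists called were 14, 13, 9, 14, 17 and 16 with a preset correlation, which lies below the estimate for each list it called, 2 in stathmin knock-out against wild type with only the genotypes compared (skeletal muscle, and neurons and glia), and 0 to 1 without single arrays in the last 3 comparisons (neurons and glia, without double knock-out 2). The shared change of 0.733, 0.555 and 0.393 became 0.458, 0.285 and 0.124 with each knock-out set against other wild type arrays, where the changes share no array. In most of these splits the like arrays wild type 3 and 4 lay on different sides, so the controls may still be much the same. The other causes were not tested. Of 2227 values of named genes, 2169 kept their direction and side of the threshold, 31 passed only in the alternative, 7 passed only in the reported setting (all Rpl11 in stathmin knock-out), and 20 uncalled values (Stmn1 and Cdkn1b in the interaction) changed sign; 2 more did among the targeted genes (Stmn1 in double knock-out against wild type, above), and 0 called values did. Aquantile between arrays leaves ratios as they are and so tests nothing. List tests with slide as a random block or with sex terms were not run. Signal over background limits the genes tested: 59.3 to 78.9% of spots were well above background.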

Other observations

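All tests of explanations in this part were chosen after the results were seen, except the test on wild type 3 and 4 and the splits for the count of genes in stathmin knock-out against wild type. Lysosome and autophagy genes, not described so far, had 27 of 31 members above 0 in stathmin knock-out against wild type, with a median of 0.19 and 0 called; the lysosomal protease gene Ctsd differed by 0.72 (SE 0.292). The list was called with a preset correlation and had adjusted p = 0.418 with an estimated correlation. Hypoxia and glycolysis genes had 24 of 25 members above 0 in p27 knock-out, with a median of 0.48 and 0 called; Pfkfb3, a regulator of glycolysis, differed by 1.29 (SE 0.652), and adjusted p was 0.836 with an estimated correlation. The list mean was above 0 on p27 knock-out 2 and 3 but -0.49 and -0.65 on the other p27 knock-out arrays, below all wild type arrays, and within slides it ran from -0.25 to 1.48. Immediate-early genes of MAP kinase signalling had 28 of 34 members below 0 in double knock-out against wild type, with a median of -0.58 and 0 called, among them Egr1 at -1.13 (SE 0.786) and Ier2 at -1.32 (SE 0.672). Within slides the list difference ran from -1.60 to 0.61, and adjusted p was 0.889 with an estimated correlation.

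The first pattern is the lower Rpl11 ratio in stathmin knock-out. A lower Rpl11 level in the sample RNA is in line with a sample-channel difference of -0.47 (SE 0.139), which leaves most of the ratio difference of -1.68 to the reference channel. Very bright spots, where a channel may gain as the other loses, are another candidate explanation. Rpl11 follows directly on the 100 brightest genes. Over the 100 brightest other genes the sample-channel and reference-channel differences correlated at -0.449 (bootstrap 95% interval over genes -0.612 to -0.223), against 0.185 over the other genes. This test replaced a slope of -0.768 on the ratio, which noise alone makes negative. The correlation was -0.457 (-0.657 to -0.289) in p27 knock-out against wild type, where Rpl11 differed by 0.03. It was -0.379 (-0.645 to 0.0721) and -0.225 (-0.473 to -0.00324) in double knock-out against wild type and p27 knock-out, where Rpl11 differed by -1.53 and -1.55. The bootstrap drew genes on the same arrays, so it does not measure the spread between arrays. The intervals overlap, so whether the correlation differs between comparisons is not shown. In p27 knock-out the correlation came without an Rpl11 difference, so by itself it does not account for that difference. Another reference pool on the stathmin knock-out arrays would be expected to show in more genes: 0 genes other than Rpl11 differed in the reference channel (limma, 308 at an unadjusted p under 0.05), and in double knock-out against each other genotype 1 gene did, Slc6a15 and not Rpl11, but a pool that differs in few genes stays open. Both the sample level and the bright spots stay open, and they are not exclusive.

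The second pattern is that genes next to the knocked-out gene differed from wild type. In stathmin knock-out, 5 of the 50 tested genes around Stmn1 had an unadjusted p under 0.01, among them Pdik1l, Mtfr1l, Runx3 and Fuca1. A share of 0 of 14146 other windows had as many (highest 4). With 50 genes to each side there were 8, Rpl11 and E2f2 among them. In p27 knock-out 7 around Cdkn1b did, among them Pbp2 and Pde6h, again a share of 0 (highest 4). In stathmin knock-out 3 around Cdkn1b did (share 0.011), namely Klrd1 (-1.17), Ybx3 (-0.80) and Pde6h (-0.93). These 3 are also among the 7 in p27 knock-out, at -1.25, -0.87 and -1.19, so they do not follow the p27 allele alone. Both comparisons use the same wild type arrays. Windows overlap and are not independent. These shares argue against slide position, which does not follow gene order. A segment of other strain origin carried along with each allele may account for it: double knock-out against wild type had 3 genes around Stmn1 (share 0.00127) and 2 around Cdkn1b (share 0.03), but the comparison that holds the other gene equal gave 1 gene around Stmn1 in double against p27 knock-out (share 0.18; 0.0262 with 50 genes to each side) and 0 around Cdkn1b in double against stathmin knock-out (share 1), so this stays open, as do effects of the alleles on their neighbours, which were not tested; of the 4 other probes of these genes around Stmn1, 1 differed the same way at an unadjusted p under 0.05 and that of Pdik1l the opposite way (-0.56), and the other Pde6h probe differed by -0.21 against -1.19 in p27 knock-out, which leaves a variant under the probe itself open too.

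The third pattern is that wild type 3 and 4 were closer to each other than any other pair: their correlation across genes was 0.815, against at most 0.628 for the other 104 pairs. RNA of 1 culture on both arrays could give this. The sample channels of this pair differed 1.49 times as much as the reference channels, the lowest of 105 pairs (next 2.32; lowest of the other wild type pairs 2.67), yet the same RNA would give a ratio near 1, so littermates or cultures handled together cannot be told apart from it. With the pair averaged, limma called 1 gene in stathmin knock-out against wild type and 0 in the other 5 comparisons.

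Other splits of the same arrays were compared with each count. In stathmin knock-out against wild type, the real count of 1 gene was reached by 1 of 35 splits, the real one. That share is the smallest 35 splits can give and is not corrected over the comparisons, so chance is not excluded for that count. The highest count of the other splits was 0, but the call was lost when any 1 of 5 arrays was left out (adjusted p = 0.0663 to 0.107). For the other counts of genes the real count is 0, which every split reaches, so the splits say nothing about chance there: 35 of 35 in p27 knock-out against wild type (highest other 0), double knock-out against wild type (0), against p27 knock-out (98) and against stathmin knock-out (5), and 100 of 100 in the interaction (48). The same holds for lists, with a real count of 0 (35 of 35 splits, or 100 of 100 in the interaction) and highest others of 1, 0, 0, 2, 0 and 1. Genes at an unadjusted p under 0.05 were as many as the real 1074, 889, 435, 555, 728 and 1372 in 12, 11, 17, 30, 17 and 20 of the splits. The split that called 98 genes set double knock-out 1, p27 knock-out 2 and p27 knock-out 3 against the other arrays of these genotypes, and 9 of the 39 interferon genes were among the 98. So many calls point to a structure of the samples; what it is was not tested, and the split was picked as the highest of 35.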
